A study of Rattus norvegicus with 16 samples.

How the data were processed

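Small RNA libraries were made from dorsal raphe or amygdala tissue of high and low responder rats, with 4 samples for each region and line and 16 samples in all. Per the labels' protocols, RNA was isolated with miRNeasy kits, libraries were made with an Illumina small RNA kit and size-selected on a Pippin instrument, and the rats were 60 days old. The deposited values are read counts per mature miRNA, with 1 table of 722 rat miRNAs for each library. The submitters' processing notes name cutadapt 1.3.1, Bowtie2 without a version and bedtools 2.14.2, without their settings. The genome build, the annotation and the treatment of reads that match several miRNAs are not given in the sources used here, so no coordinates are printed. Values of near-identical mature sequences, such as miR-204-5p and miR-211-5p, miR-101a-3p and miR-101b-3p, miR-10a-5p and miR-10b-5p, miR-133a-3p and miR-133b-3p or miR-99a-5p and miR-100-5p, are uncertain to the extent that reads were split between them.

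The counts were used as deposited. Whole numbers and totals that differ between libraries showed that the values were not normalised. Totals ran from 1741167 to 8134915 counts. The lowest chi-square per degree of freedom was 55.4 over all 120 pairs of libraries, so no library was a copy of another. miRNAs of low count were left out with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 639 and dropped 83; the latter held at most 0.0169% of the counts of a library. Levels are CPM scaled by trimmed mean of M values (TMM) factors, and log2 CPM uses a prior count of 2. The factor was 0.596 in low responder dorsal raphe replicate 4, which raises its scaled levels, and 0.870 to 1.27 in the other libraries. Percentages of a library are of its unscaled counts.

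Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust moderation, in 1 model with a mean for each of the 4 groups, so that all 16 libraries share the estimate of the spread. The biological coefficient of variation was 0.426. Tested were the line difference (high over low responders) in each region, the interaction of line and region, the region difference (amygdala over dorsal raphe) averaged over the lines and the region difference in each line. P-values were adjusted by Benjamini-Hochberg over all miRNAs tested, with a threshold of 0.05. The 21 lists of miRNAs (cell types, regions, families and genomic clusters) were tested with camera and fry of limma 3.58.1 on voom weights. Lists were written from background knowledge. Differences of a list mean or of the miR-101 miRNAs between 4 and 4 libraries were tested with an exact two-sided permutation test. Where the numbers were taken to pair the libraries, the signs of the pair differences were permuted as well. Correlations over libraries were tested by permutation within groups.

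The miRNAs named are, for each comparison, those past the threshold with a mean of at least 10 CPM, up to 12 higher and 12 lower by size of the log2 fold change. Where fewer than 10 passed, the 10 of lowest p were named. Up to 4 members of each list, those of lowest p, and the 2 miR-101 miRNAs were added, and the 10 most abundant miRNAs. The miRNAs encoded in the serotonin 2C receptor gene were grouped after their values were seen. Tests, groups, lists, the naming rule and the first set of alternative analyses were fixed before the data were examined.

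The labels number the libraries of each group 1 to 4. Same-numbered libraries of low and high responder amygdala deviated together from their group means, with correlations across miRNAs of 0.69, 0.29, 0.21 and 0.51, all above the 0.1 set as the criterion, and so the numbers were taken to pair these libraries. In both groups replicates 1 to 4 also lie in that order on the main axis of variation within groups, which holds 56.9% of that variation. Such an order could give these correlations without a shared rat or batch, and no test over other matchings was run. The labels do not say what a number stands for, nor that the samples of a group came from separate rats, so p-values measure the spread between these samples. In the other pairs of groups at least 1 correlation was not above 0.1.

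The line difference in each region and the averaged region difference were tested on simulated counts. These were drawn from the real means, dispersions and library totals, with 200 miRNAs changed by 1.5-fold, 2-fold or 4-fold. The interaction and the region difference in each line were not simulated. Percentages are of the changed miRNAs that passed the low count filter, 62 to 67 for each size of change. edgeR found 6.45%, 24.2% and 80.3% of these for the line difference in dorsal raphe (621 miRNAs; 73 called, 0 falsely), 6.06%, 32.3% and 87.9% in amygdala (617 miRNAs; 86 called, 3 falsely) and 22.4%, 71.9% and 98.4% for the region difference (613 miRNAs; 127 called, 4 falsely). In 10 draws over 639 miRNAs for the line difference in amygdala, camera called 0 of 210 unchanged lists and in all 10 draws the list changed by 2-fold. The simulated miRNAs vary independently, so this does not test correlated lists.

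This first set held the DESeq2 1.42.0 Wald test, limma-voom, the size factors of DESeq2 (RLE) and library totals in place of TMM factors, no low count filter, a filter at a mean of 10 CPM, no robust moderation, only the libraries compared, the replicate number as a block, an adjusted p threshold of 0.10, each library left out in turn, the estimated correlation and fry for the lists, and for miR-101a-3p the share among counts outside the 10 most abundant miRNAs. Added after the data were seen were libraries of over 3000000 counts alone, the log2 total as a covariate, leaving out both shallowest libraries, leaving low responder dorsal raphe replicate 4 out of the shared spread, leaving out 2 low responder libraries that stood apart in their regions, and each library left out in the list tests. The cut at 3000000 counts removes low responder dorsal raphe replicate 4, high responder dorsal raphe replicate 1 and high responder amygdala replicates 1 and 2. Figures were drawn with matplotlib 3.10.9 in Python. No library was left out of the main analysis.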

Results

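Mature microRNAs (miRNAs, short RNAs that repress messenger RNAs) were counted by small RNA sequencing in the dorsal raphe, the midbrain nucleus that supplies serotonin to the forebrain, and in the amygdala, a forebrain region for fear and emotional learning. The rats came from 2 lines bred for high or low locomotor response to a new environment, called high responders and low responders, and were 60 days old. Each of the 4 combinations of line and region had 4 libraries, 16 in all. The libraries held 1741167 to 8134915 counts over the 722 miRNAs listed. At this depth 3 counts, the floor below which a level is not told from absence, stood for 0.369 to 1.72 counts per 1000000 (CPM), a limit that covers counting error only.

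miR-9a-5p, a neural progenitor and neuron miRNA, was the most abundant miRNA in every library, with a mean of 13.5% of the counts. miR-26a-5p (4.94%), the neuronal miR-128-3p (4.73%), the imprinted miR-127-3p (3.98%) and miR-99a-5p (3.44%) followed, and then miR-7a-5p, miR-181a-5p, let-7f-5p, miR-143-3p and let-7i-5p. The first principal component of log2 CPM held 47.0% of the variance and the second 20.1%. Low responder dorsal raphe replicate 4 and high responder amygdala replicate 1, with 2096188 and 1741167 counts the lowest of their groups, lay far from their groups. Their root mean square deviations from their group means were 1.03 and 0.968 on the log2 scale, against 0.285 to 0.880 for the remaining 14 libraries, of which high responder amygdala replicate 4 had the 0.880. Within groups, the place of a library on the main axis of variation fell with the log2 of its total count (Pearson r = -0.894, permutation p = 0.00074; Spearman rho = -0.841, permutation p = 0.00295). Without the 2 libraries farthest from the median the r was -0.857.

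**Figure D1:**
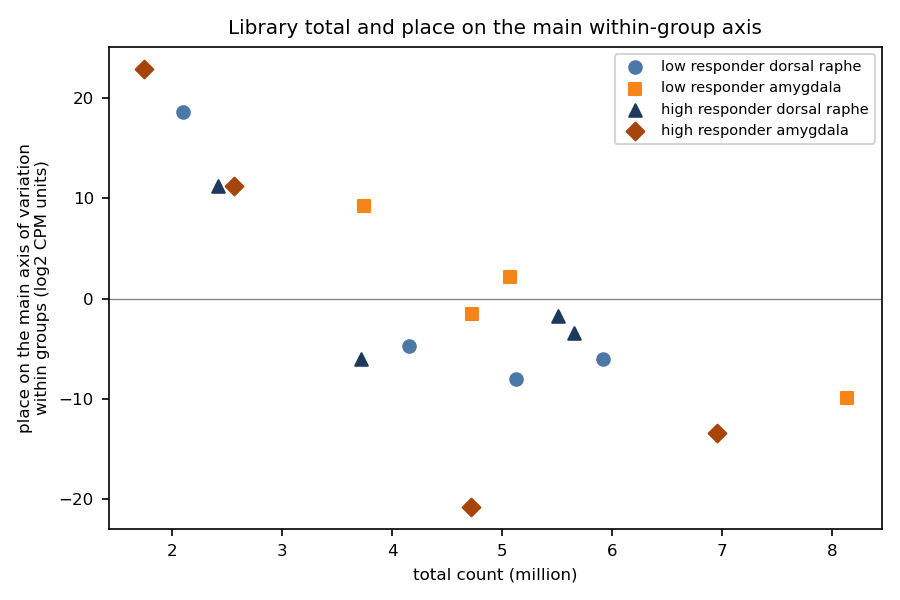
Total count of each library (horizontal axis) against its place on the main axis of variation within groups, in log2 CPM units (vertical axis), with 1 point per library and symbols for the 4 groups. The libraries of 1741167 and 2096188 counts sit at 22.9 and 18.7, and the library of 8134915 at -9.90, while high responder amygdala replicates 4 and 3, of 4713850 and 6949748 counts, lie lowest at -20.8 and -13.4.

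The comparison of amygdala with dorsal raphe shows which miRNAs mark each region in these rats. miRNAs encoded within the gene of the serotonin 2C receptor had the largest rises in amygdala. miR-1298 averaged 22463 ± 12350 CPM there against 1386 ± 836 in dorsal raphe (SD, n = 8 libraries each), a 16-fold rise, and miR-1912-3p (12.4-fold) and miR-448-3p (7.59-fold) rose with it. The mean log2 CPM of the 6 miRNAs of this gene was 4.44 in low responder amygdala replicate 4, below all 8 raphe libraries (4.95 to 5.55), and 6.12 to 7.71 in the other 7 amygdala libraries. Over the amygdala libraries it went with the mean of the choroid plexus miRNAs (r = 0.942 within lines, exact permutation p = 0.0104; r = 0.672 without the 2 libraries farthest from the median). miR-10b-5p, which lies in a Hox cluster and marks hindbrain, was 19.8-fold lower in amygdala (25.3 ± 18.5 against 556 ± 830 CPM). The muscle miRNAs miR-133a-3p and miR-1-3p were 7.61-fold and 6.50-fold lower.

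Averaged over the lines, 60 of the 639 miRNAs tested were higher and 95 lower in amygdala at an adjusted p of 0.05 in edgeR's quasi-likelihood test. Of these, 92 differed by more than 2-fold, and 42 had no overlap between the 8 libraries of either region, where chance gives 0.0155% of all miRNAs. DESeq2, with its own scaling, called 198, with 98 higher and 100 lower. Among those that rose, miR-221-3p (log2 fold change 2.90, SE 0.38, adjusted p = 2.6e-05) and miR-222-3p (2.36, SE 0.19), which are transcribed together, rose with the other arm, miR-221-5p (2.06). miR-139-5p (2.72, SE 0.22) and miR-139-3p (2.11), from an intron of the phosphodiesterase gene Pde2a, rose too. The neuronal miR-128-3p (2.23, SE 0.22) rose from 16519 ± 7363 to 78690 ± 22054 CPM, and miR-128-2-5p (1.78), miR-504 (1.92) from the Fgf13 gene and miR-204-5p (1.79, SE 0.35) from the Trpm3 gene rose as well.

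Among the miRNAs that were lower in amygdala, miR-653-5p, from the calcitonin receptor gene, had the lowest adjusted p of all (8.6e-09; log2 fold change -3.72, SE 0.25). miR-34a-5p, which p53 induces, fell by 3.15 (SE 0.40), from 1489 ± 507 CPM in dorsal raphe to 169 ± 85.6 CPM. miR-96-5p (-2.98) and miR-183-5p (-2.84), of a cluster known from sensory organs, were lower, and so were miR-10a-5p (-2.31), the second Hox cluster miRNA, miR-133b-3p (-2.35), miR-298-5p (-2.50), miR-3547 (-2.33) and miR-217-5p (-2.20). miR-10b-5p and miR-1-3p stood at 2610 and 4697 CPM in low responder dorsal raphe replicate 4, against 240 to 316 and 972 to 1511 CPM in the other 7 raphe libraries. The low TMM factor of that library, 0.596, raises both levels. Without that library the log2 fold changes of miR-10b-5p and miR-10a-5p were -3.43 and -1.54, and both still passed the test.

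**Figure D2:**
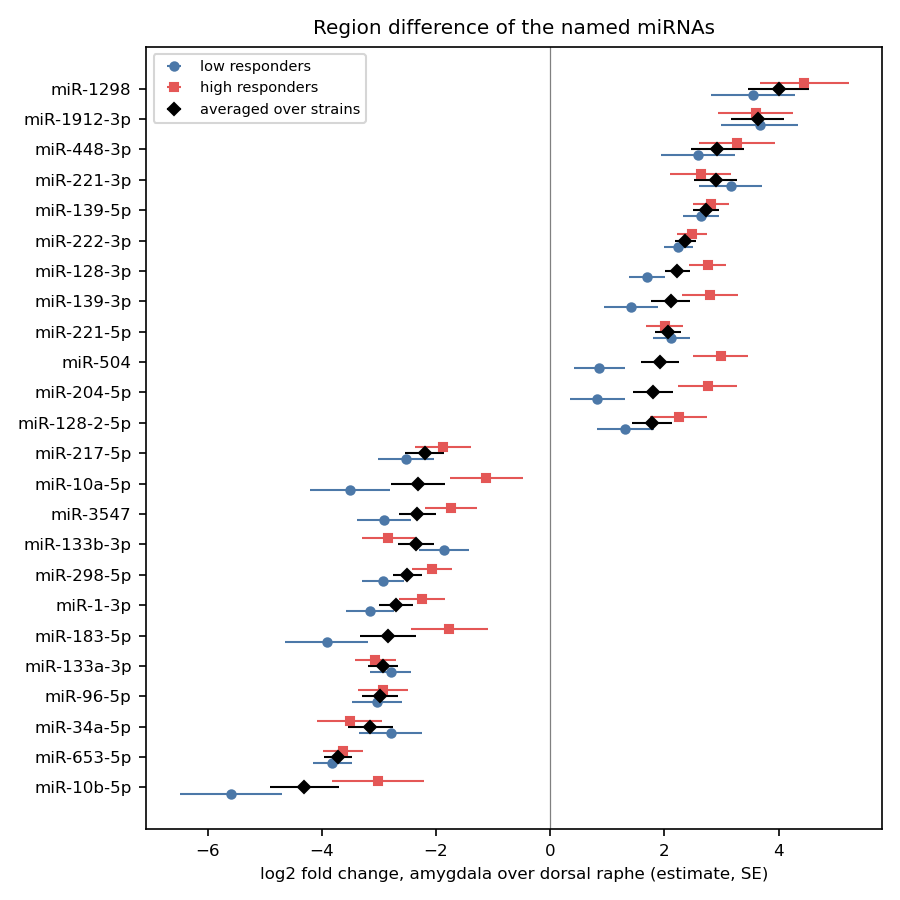
Log2 fold change of amygdala over dorsal raphe for the 12 miRNAs with the largest rise and the 12 with the largest fall, with bars of 1 SE, in low responders (circles), high responders (squares) and averaged over the lines (diamonds). miR-1298 stands highest at 4.00 and miR-10b-5p lowest at -4.30, and in each miRNA both lines have the same direction.

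Of the 21 miRNA lists tested with camera, which compares a list with all other miRNAs at a preset correlation of 0.01, 7 differed between the regions, and none of the 7 passed when the correlation was estimated per list. Neuron-enriched miRNAs rose: 6 of 18 were higher and none lower, among them miR-132-3p (1.73) and miR-212-3p (1.16), which neuronal activity induces (list median 0.38, adjusted p = 0.00439; adjusted p = 0.675 with an estimated correlation). Forebrain-enriched miRNAs rose, with 6 of 12 higher and 2 lower, the latter miR-34a-5p and miR-135a-5p (-1.95) (median 0.86, adjusted p = 0.0110; adjusted p = 0.675 with an estimated correlation). This list shares miR-132-3p, miR-212-3p and further members with the neuron-enriched list, so these rises are not separate results. Choroid plexus and ciliated cell miRNAs rose, with 5 of 12 higher, among them miR-211-5p (1.68) and miR-204-3p (1.02) (median 1.27, adjusted p = 0.0110; adjusted p = 0.675 with an estimated correlation). Muscle miRNAs fell, with 6 of 9 lower, including miR-206-3p (-1.89), and 1 higher (median -1.58, adjusted p = 0.00847; adjusted p = 0.0926 with an estimated correlation). Oligodendrocyte miRNAs fell, with 4 of 7 lower, including the myelin miRNA miR-338-3p (-1.18) (median -0.87, adjusted p = 0.0446; adjusted p = 0.675 with an estimated correlation). Of the imprinted Dlk1-Dio3 cluster, 23 of 91 miRNAs were lower, such as miR-758-3p (-1.81), miR-134-5p (-1.41), miR-666-5p (-1.42) and miR-382-3p (-1.08), and 4 were higher (median -0.34, adjusted p = 0.0446; adjusted p = 0.675 with an estimated correlation). Of the miR-181 family 5 of 10 fell, including miR-181d-5p (-1.03), miR-181c-5p (-1.23) and miR-181c-3p (-0.77) (median -0.63, adjusted p = 0.0478; adjusted p = 0.675 with an estimated correlation).

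The fry test, which asks whether the miRNAs of a list move on balance one way, gave 8 lists, and its test for change in either direction gave 10. With the fits that left out 1 library at a time camera gave 3 to 7 lists, with 3 without low responder amygdala replicate 2 and 4 without low responder amygdala replicate 1 or without high responder amygdala replicate 2. Libraries of over 3000000 counts alone gave 3.

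The other 14 lists did not pass in camera. Members of several moved apart. Activity-regulated neuronal miRNAs had 4 higher and 5 lower of 13 (median -0.12, adjusted p = 0.814), and the epithelial and pituitary list had 4 higher, such as miR-200b-3p (1.41) and miR-200a-3p (1.43), and 3 lower of 16 (median 0.83, adjusted p = 0.321). Of the miRNAs reported in stress, anxiety or serotonin work 2 of 22 were higher and 6 lower (median -0.33, adjusted p = 0.341), and of those reported to target the chromatin enzyme Ezh2 1 of 9 was higher and 1 lower (median -0.22, adjusted p = 0.959). The vascular list had 1 of 8 lower, miR-195-5p (-1.89) (median -0.60, adjusted p = 0.0833), the Hox cluster list 2 of 6 (median 0.05, adjusted p = 0.368) and the microglia and leukocyte list 2 of 9 (median -0.24, adjusted p = 0.356). Of the astrocyte (median -0.36, adjusted p = 0.321), miR-29 (median -0.66, adjusted p = 0.321) and miR-466 and miR-297 repeat cluster lists (median 0.33, adjusted p = 0.636) 1 miRNA each was lower. The erythrocyte (median 0.12, adjusted p = 0.959), let-7 (median -0.30, adjusted p = 0.383), miR-30 (median -0.33, adjusted p = 0.635) and miR-17-92 lists (median -0.13, adjusted p = 0.959) had no miRNA past the threshold. Median, mean and test direction differed in sign for the activity-regulated, erythrocyte, Hox cluster and miR-17-92 lists. The choroid plexus miRNAs also differed between amygdala libraries of the same line, with a mean log2 CPM of 5.29 ± 1.36 in low responders (SD, n = 4). Replicate 4 stood at 3.36 and replicates 1, 2 and 3 at 5.52, 6.55 and 5.74, while high responders had 6.43 ± 0.28.

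Within low responders 90 miRNAs differed between the regions, 23 higher and 67 lower in amygdala (39 and 66 with DESeq2, 34 and 54 with library totals as the scaling), and within high responders 84, with 42 in each direction (40 higher and 71 lower with library totals). miR-1298 rose in both (log2 fold change 3.55, SE 0.74, and 4.45, SE 0.77) and miR-10b-5p fell in both (by 5.59, SE 0.90, and 3.02, SE 0.80). The fall of miR-10b-5p in low responders rests in part on dorsal raphe replicate 4, at a log2 CPM of 11.4 against 7.91 to 8.09 in the others of its group. The 38 miRNAs called in both lines all had the same direction, where independent lists would share 5.92 miRNAs of the same direction. A call in 1 line alone does not show a difference between the lines, and the test of that difference, the interaction below, gave 0 calls. Without low responder amygdala replicate 3 the low responders gave 47 calls, and without high responder amygdala replicate 4 the high responders gave 72 higher and 56 lower.

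The comparison of the lines within dorsal raphe asks which miRNAs go with the bred trait in the region of serotonin neurons. The 10 miRNAs with the lowest p were all at lower levels in high responders, and none passed. miR-92a-3p, of the miR-17-92 family, stood at 450.8 ± 24.8 CPM in high responders against 901.0 ± 342.3 in low responders (SD, n = 4 each; log2 fold change -1.0, SE 0.28, adjusted p = 0.358 in edgeR). miR-100-5p stood at 9633 ± 1394 against 30371 ± 38264 CPM (-1.66, SE 0.56) and miR-219-2-3p, an oligodendrocyte miRNA, at 6181 ± 222.97 against 15199 ± 13453 CPM (-1.30, SE 0.44). The neuronal miRNAs of the Dlk1-Dio3 cluster miR-485-5p (-1.94), miR-409a-3p (-1.41) and miR-543-3p (-0.80), and miR-6321 (-2.44), miR-125b-1-3p (-0.97), miR-30c-2-3p (-1.46) and miR-6331 (-1.29), made up the rest.

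edgeR called 0 of 639 miRNAs between the lines in dorsal raphe, with 70 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With no difference a share of about 0.05 of the miRNAs tested would lie there, more or fewer where miRNAs vary together. The 70 became 76, 76, 71 and 23 without low responder replicates 1, 2, 3 and 4, and 41, 27, 39 and 43 without high responder replicates 1, 2, 3 and 4. Groups without overlap were seen for 27 miRNAs (4.23%, where chance gives 2.86%). As a group the Dlk1-Dio3 cluster fell in high responders (median log2 fold change -0.25, 22 of 91 positive, camera adjusted p = 0.00325; adjusted p = 0.986 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. miR-382-5p of this cluster had -0.95 (SE 0.33). The cluster's mean log2 CPM differed by -0.22 between the lines, with an exact permutation p of 0.0571 (two-sided, n = 4 each, the smallest possible being 0.0286). Its call was lost without low responder replicate 1 (adjusted p = 0.0559), low responder replicate 3 (0.0706) or high responder replicate 1 (0.113). The other 20 lists had adjusted p from 0.0790, for the erythrocyte list (median 0.32, 5 of 6 positive), to 0.990. Adjusted over the list alone, 1 miR-17-92 family member was lower. Median, mean or test direction differed in sign for the epithelial, Ezh2, Hox cluster, miR-29, muscle and stress lists. Without low responder dorsal raphe replicate 4 all of these miRNAs lay closer to 0: miR-100-5p at -0.09, miR-6331 at -0.15, miR-485-5p at -0.20, miR-382-5p at -0.23, miR-30c-2-3p at -0.27, miR-409a-3p at -0.28, miR-219-2-3p at -0.32, miR-543-3p at -0.51, miR-125b-1-3p at -0.54, miR-92a-3p at -0.56 and miR-6321 at -1.85. In simulated counts for this comparison, over 621 miRNAs, the test found 24.2% of 2-fold changes and 80.3% of 4-fold changes.

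**Figure D3:**
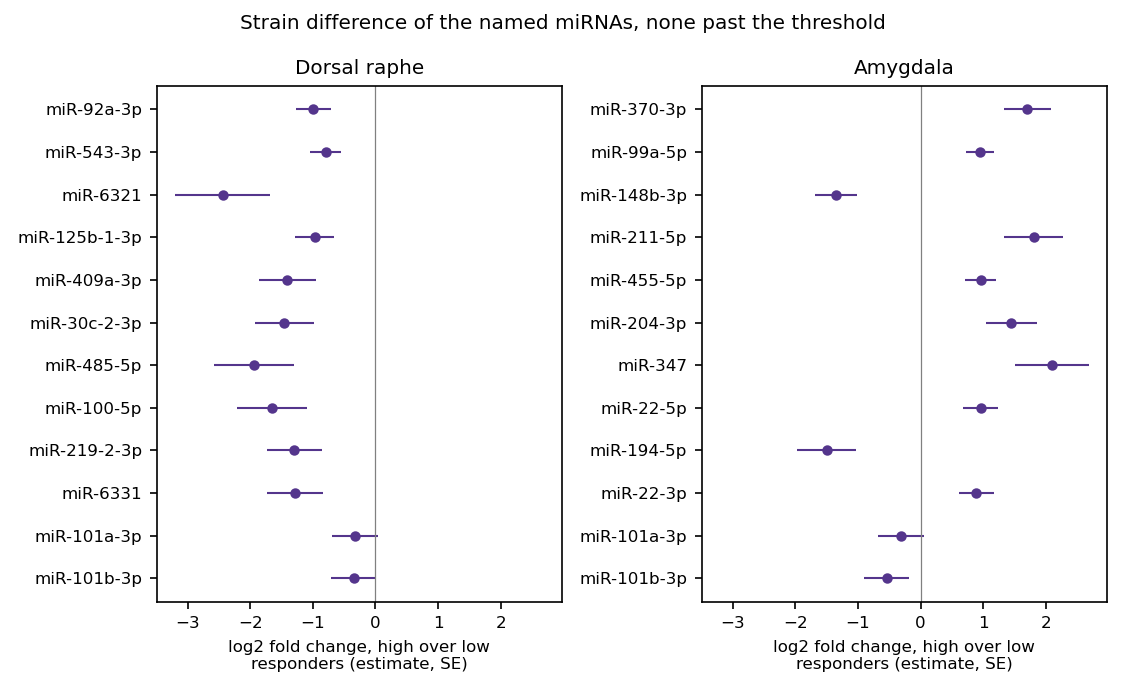
Log2 fold change of high over low responders, with bars of 1 SE, in dorsal raphe (left) and amygdala (right) for the 10 miRNAs of lowest p in each region and for miR-101a-3p and miR-101b-3p. None passed an adjusted p of 0.05; the first entries are miR-92a-3p at -1.0 and miR-370-3p at 1.71.

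In amygdala the same question was asked of the region tied to fear behaviour. miR-370-3p, of the Dlk1-Dio3 cluster, stood at 1854 ± 857 CPM in high responders against 569 ± 117 in low responders (SD, n = 4 each), and miR-99a-5p at 47262 ± 8321 against 24468 ± 2203. miR-148b-3p went the other way, with 2064 ± 815 against 5271 ± 1489 CPM. None of them passed the test. The choroid plexus miRNA miR-204-5p, expressed in the epithelium that makes cerebrospinal fluid, stood at 12898 ± 3603 CPM in high responders and 4523 ± 3596 in low responders, with 942 CPM in low responder replicate 4. miR-211-5p, near-identical to it in sequence, stood at 544.4 ± 148 and 156 ± 112 CPM, and in all 16 libraries its counts were 3.01% to 4.77% of those of miR-204-5p.

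edgeR called 0 of 639 miRNAs between the lines in amygdala, with 65 at an unadjusted p under 0.05, while DESeq2 called 19 (14 higher and 5 lower) and limma-voom 0. The 65 became 71, 58, 46 and 53 without low responder replicates 1, 2, 3 and 4. Without high responder replicates 1, 2, 3 and 4 the count was 47, 46, 65 and 102. The lowest adjusted p were those of miR-370-3p (0.126; log2 fold change 1.71, SE 0.38), miR-99a-5p (0.126; 0.95, SE 0.22), miR-148b-3p (0.140; -1.35, SE 0.33), miR-211-5p (0.183; 1.80, SE 0.47) and miR-455-5p (0.183; 0.96). miR-204-3p (1.45), miR-347 (2.09), miR-22-5p (0.96), miR-194-5p (-1.5) and miR-22-3p (0.89) came next. Groups without overlap were seen for 56 miRNAs (8.76%, where chance gives 2.86% if the libraries are freely exchangeable, which ignores the pairing by number). Leaving out both shallowest libraries of the study gave 9 calls, among them miR-370-3p, miR-22-5p, miR-22-3p, miR-455-5p and miR-99a-5p higher and miR-148b-3p lower in high responders. In simulated counts for this comparison, over 617 miRNAs, edgeR found 32.3% of 2-fold changes and 87.9% of 4-fold changes.

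Of the lists, the choroid plexus and ciliated cell miRNAs were higher in high responder amygdala (median log2 fold change 0.76, 11 of 12 positive, camera adjusted p = 2.0e-05; adjusted p = 0.802 with an estimated correlation). Of its members 0 passed over all miRNAs and 3 passed when adjusted over the list alone, miR-211-5p, miR-204-3p and miR-204-5p (1.51, SE 0.49). The ciliated cell miRNAs miR-34b-5p (1.15, SE 0.71) and miR-449a-5p (0.86, SE 0.53) did not, and the latter lay at 0.35 without high responder replicate 4 and at 1.88 without low responder replicate 2. The list's mean log2 CPM was 1.13 higher in high responders, with an exact permutation p of 0.114 (two-sided, n = 4 each), and 0.49 higher (SE 0.34) without low responder replicate 4. In the 4 pairs of libraries with the same number it was higher by 0.60, 0.25, 0.71 and 2.98 (exact permutation p of the signs 0.125, the smallest possible). With the replicate number as a block, taken here to pair libraries, 2 lists passed, and this one had an adjusted p of 7.9e-05. Libraries of over 3000000 counts alone gave 0 lists, and the fits without 1 library gave 1 to 5, with 5 without high responder replicate 3 and 2 without low responder replicate 4 or high responder replicate 4. The other 20 lists had adjusted p from 0.225, for the forebrain list, to 0.851. Of the Dlk1-Dio3 list 1 member, higher in high responders, also passed when adjusted over the list alone.

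**Figure D4:**
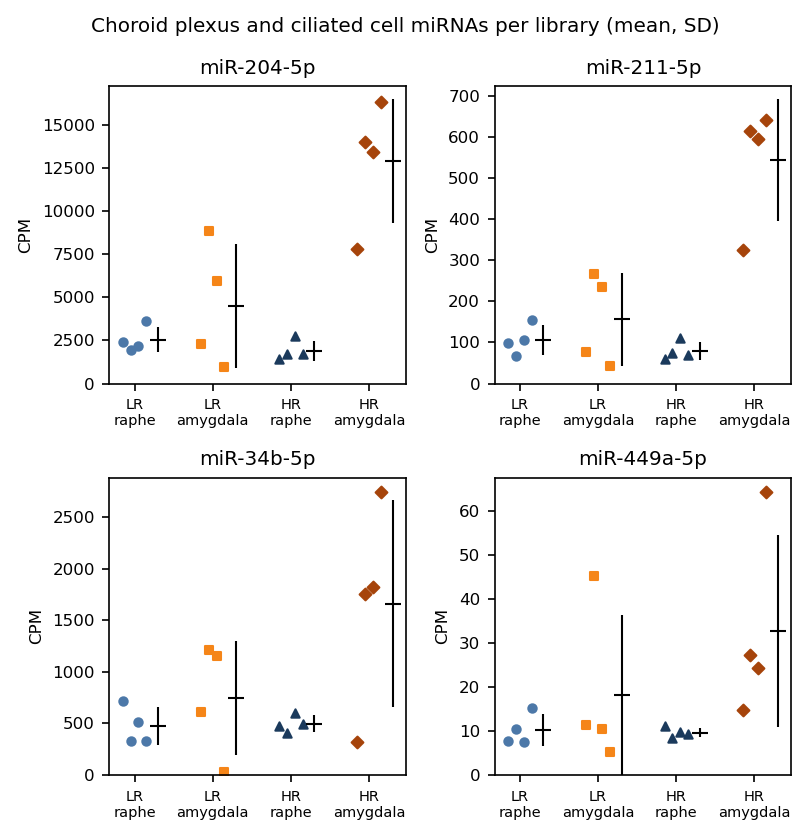
Normalised CPM of the choroid plexus miRNAs miR-204-5p and miR-211-5p and of the ciliated cell miRNAs miR-34b-5p and miR-449a-5p in each library, by group (LR, low responders; HR, high responders), with the group mean and SD beside the points. miR-204-5p lies between 7832 and 16331 CPM in the 4 high responder amygdala libraries and between 942 and 8887 in the 4 low responder ones.

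The interaction asks whether the line difference itself differs between amygdala and dorsal raphe. miR-370-3p came closest, with a log2 difference of 2.7 (SE 0.53) between the amygdala and raphe line differences and an adjusted p of 0.0514 in edgeR. miR-125b-1-3p (1.90), miR-320-5p (2.05), let-7b-3p (2.21), miR-347 (3.03), miR-423-3p (1.5), miR-22-3p (1.39), miR-770-3p (2.78), miR-485-5p (3.05) and miR-188-5p (3.09) followed, at adjusted p from 0.141 to 0.195. edgeR called 0 miRNAs, with 81 at an unadjusted p under 0.05, DESeq2 called 17 and limma-voom 0. The interaction was not tested in simulated counts. Its median SE was 0.578, against 0.411 and 0.410 for the line differences in dorsal raphe and amygdala. Without low responder dorsal raphe replicate 1 or high responder amygdala replicate 4 edgeR called miR-370-3p alone (adjusted p = 0.0482 and 0.0336). Without low responder dorsal raphe replicate 4 all 10 were smaller: miR-370-3p 2.01 (adjusted p = 0.0708), miR-347 2.15, miR-188-5p 1.80, let-7b-3p 1.61, miR-770-3p 1.59, miR-125b-1-3p 1.44, miR-320-5p 1.37, miR-485-5p 1.29, miR-22-3p 1.10 and miR-423-3p 0.94. The choroid plexus list had a larger line difference in amygdala (median 0.42, 9 of 12 positive, camera adjusted p = 0.0378; adjusted p = 0.913 with an estimated correlation), with 3 members past the threshold when adjusted over the list alone, miR-211-5p (2.24), miR-204-3p (1.79) and miR-204-5p (1.93). This call was lost without low responder amygdala replicate 4 (adjusted p = 0.314), low responder dorsal raphe replicate 1 (0.0530) or 3 (0.0676) or high responder amygdala replicate 4 (0.0560). The other 20 lists had adjusted p from 0.360 to 0.874, and median, mean or test direction differed in sign for the let-7, neuron-enriched, repeat cluster and stress lists. Adjusted over the list alone, 2 activity-regulated miRNAs and 1 of the Dlk1-Dio3 cluster passed as well.

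miR-101a-3p, which represses the chromatin enzyme Ezh2, is the miRNA the study followed in amygdala, so its direction here is not independent evidence. In amygdala it stood at 13147 ± 1073 CPM in high responders and 16318 ± 2923 in low responders (SD, n = 4 each), a log2 fold change of -0.31 (SE 0.37, adjusted p = 0.769 in edgeR). The exact permutation test on log2 CPM gave p = 0.0571 (two-sided, the smallest possible being 0.0286). miR-101b-3p, of near-identical sequence, stood at 3804 ± 176 against 5544 ± 912 CPM with no overlap between the lines (log2 fold change -0.54, SE 0.36, adjusted p = 0.674; exact permutation p = 0.0286, the smallest possible). Paired by number, miR-101a-3p was lower in 3 of 4 pairs and miR-101b-3p in all 4 (exact permutation p of the signs 0.25 and 0.125, the latter the smallest possible). In dorsal raphe the log2 fold changes were -0.33 (SE 0.37) and -0.35 (SE 0.36). Without low responder replicate 4 they were 0.53 and 0.49. In that library miR-101a-3p reached 41732 CPM, a level raised by the library's low TMM factor of 0.596. The interaction was 0.01 (SE 0.52) for miR-101a-3p and -0.20 (SE 0.51) for miR-101b-3p, and the region difference was -0.22 (SE 0.26) and -0.35 (SE 0.25). None of these passed the test.

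**Figure D5:**
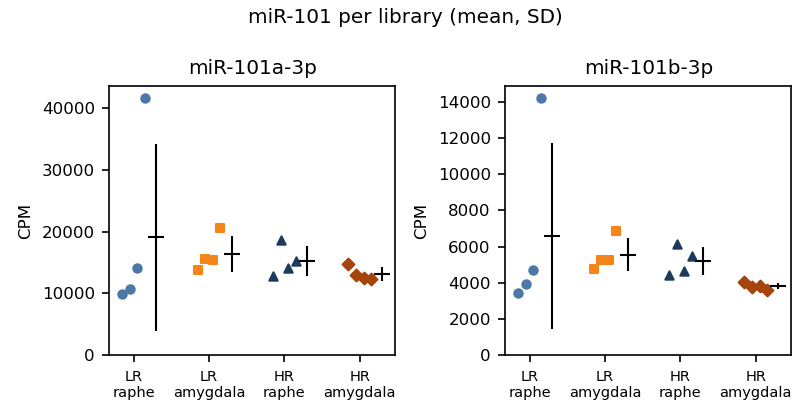
Normalised CPM of miR-101a-3p (left) and miR-101b-3p (right) in each library, by group (LR, low responders; HR, high responders), with the group mean and SD beside the points. In amygdala miR-101b-3p lies at 3591 to 4017 CPM in high responders and 4767 to 6864 in low responders, and low responder dorsal raphe replicate 4 stands at 41732 CPM of miR-101a-3p.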

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

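Of the tests weighed here, those of library preparation (hairpin arms included), of tissue of the other region, of 1 deciding library, of choroid plexus tissue, of shared miR-204-5p reads and of the numbered pairs were chosen only after the result was seen.

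A library far from the other 3 of its group was found by Dixon's ratio (gap to the nearest library over the range of the group) in 29 of 336 group tests, where chance gives about 5%. Among the miRNAs tested were ones named for their values in these same libraries, and the tests are not independent. The 5% is thus a rough scale only. Low responder dorsal raphe replicate 4 stood above its group in the share of counts held by the 10 most abundant miRNAs (54.0% against 41.9% to 42.5%, ratio 0.946) and in log2 CPM of miR-10b-5p (11.4 against 7.91 to 8.09, ratio 0.947), miR-10a-5p (0.927), miR-100-5p (0.927), miR-485-5p (12.3 against 8.90 to 9.28, ratio 0.886), miR-221-5p (0.944), miR-666-5p (0.935), miR-6331 (0.922), miR-181c-5p (0.910), miR-188-5p (0.886), miR-370-3p (0.877), miR-30c-2-3p (0.869), miR-382-5p (0.863) and miR-219-2-3p (0.848). Low responder dorsal raphe replicate 3 stood high in miR-338-3p (0.946) and replicate 2 low in the mean of the choroid plexus list (4.53 against 5.07 to 5.09, ratio 0.955). High responder dorsal raphe replicate 3 stood high in miR-10b-5p (0.902) and miR-128-3p (0.930), and replicate 1 low in miR-150-5p (0.909) and miR-382-5p (0.919). Low responder amygdala replicate 1 stood high in miR-133b-3p (0.875) and miR-485-5p (0.863) and low in miR-181c-5p (0.865) and miR-99a-5p (0.947), and replicate 2 high in miR-347 (0.845). High responder amygdala replicate 1 stood low in miR-211-5p (0.895) and miR-448-3p (0.904) and high in miR-485-5p (0.845). High responder amygdala replicate 4 had 34 miRNAs at 0 counts against 3 to 7 in the other libraries of its group (ratio 0.871). The line difference of the choroid plexus list differed between the regions at the preset correlation (interaction, camera adjusted p = 0.0378, but 0.913 with an estimated correlation). This call was also lost without low responder amygdala replicate 4, among other libraries.

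Low responder dorsal raphe replicate 4 and high responder amygdala replicate 1 stood apart, the first in miR-10b-5p and miR-100-5p, the second in miR-211-5p and miR-448-3p and both in miR-485-5p, at 18.7 and 22.9 on the within-group axis; high responder amygdala replicate 4, of 4713850 counts, lay at -20.8 on its other side. Thinning the other libraries of their groups to the same totals moved those by at most 0.399 (root mean square of log2 CPM, below the 0.484 that was set as the bound), against 1.03 and 0.968 for these libraries, which argues against fewer counts alone. A shift toward the other region accounted for at most 0.0598 of the squared deviation over the miRNAs past the threshold in the region difference. This argues against tissue of the other sampled region or a label swapped between the regions. Tissue from outside the 2 regions cannot register in this test and stays open, with the hindbrain miRNA miR-10b-5p high in the raphe library. The mean log2 CPM of the Hox cluster list was 4.34 there, against 3.46 to 3.60 in its group. It was also high in the amygdala library (4.10 against 1.73 to 3.57). The same held for high responder dorsal raphe replicate 1 (4.25 against 3.15 to 3.65), where miR-10b-5p was not high. A high list mean was thus not particular to the raphe library. The raphe library did lie 0.212 of the region difference toward amygdala, but the amygdala library lay 0.198 in the same direction, away from raphe. Library preparation or RNA quality in libraries of low total may contribute and stays open, since the place on the axis went with the log2 total (r = -0.894). That it acted on single mature sequences cannot be told: the 2 arms of a hairpin deviated independently in these libraries (mean r = -0.0046 over 113 hairpins), but in the 6 other libraries of their groups, measured from their own means, r was 0.240 to 0.475 in raphe and -0.204 to 0.0231 in amygdala (mean 0.106), and the state of the animal stays untested.

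The choroid plexus and ciliated cell miRNAs, led by miR-204-5p, miR-204-3p and miR-211-5p, were higher in high responder amygdala. Low responder amygdala replicate 4 had the lowest levels and cannot be ruled out as the cause: without it the list still passed at the preset correlation of 0.01 (camera adjusted p = 0.0171; over the alternatives 1.3e-09 without low responder amygdala replicate 2 to 0.802 with an estimated correlation of 0.512), but its mean differed by 0.49 (SE 0.34) in place of 1.13, though by 0.52 (SE 0.14) over the 3 other numbered pairs. Over the 8 amygdala libraries, within lines, the list's mean went with that of the 6 miRNAs of the serotonin 2C receptor gene, a receptor abundant in choroid plexus (r = 0.942, exact permutation p = 0.0104; rho = 0.786, exact permutation p = 0.0417; r = 0.672 without the 2 libraries farthest from the median); miR-1298 ran from 1092 to 38571 CPM and miR-204-5p from 942 to 16331 CPM. Between the lines the list rose by more than these miRNAs, by 0.56, 0.85, 0.61 and 0.19 in the 4 numbered pairs. The mean was 0.55 (SE 0.14), and 0.67 (SE 0.089) without pair 4. The exact permutation p of the signs was 0.125, the smallest possible with 4 pairs. With the mean of the serotonin 2C receptor gene miRNAs as a covariate the list was higher by 0.63 (SE 0.27). Without low responder replicate 4 that value was 0.52 (SE 0.20). These values do not decide whether a differing share of choroid plexus was the whole cause. They rest on at most 8 libraries, and the pair differences assume that both sets change equally with that tissue, which was not tested. Such a share, as the whole cause or a part, and a line difference in the cells themselves stay open. Of the 12 list members 7 also exceeded 10 CPM in dorsal raphe and 2 belong to another list. The log2 ratio of miR-211-5p to miR-204-5p had an SD of 0.177 over the 16 libraries, the lowest of 404 miRNAs (next 0.462, median 1.5), so that miR-211-5p may largely be miR-204-5p reads and the list then counts 1 signal 2 times. The next was miR-204-3p, the other arm of the miR-204 hairpin. The 3 members that passed when adjusted over the list alone are these miRNAs, and so are not 3 separate signals.

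In amygdala edgeR called 9 miRNAs between the lines when both shallowest libraries were left out, 7 higher (miR-370-3p, miR-22-5p and miR-22-3p first) and 2 lower, against 0 with all libraries. Chance could not be excluded: 4 of the 35 splits of the remaining 7 amygdala libraries gave as many, with 9 for the lines and 84 for the highest other split. None of the 3 others parts all 3 remaining pairs of numbers, and among the 8 splits that do, the lines gave 9 and the highest other 2, too few splits for a share under 0.05. A bias on single mature sequences, in which the arms of a hairpin would differ independently, cannot be told apart from a line difference, since the arms' line differences had r = 0.232 over 113 hairpins (permutation p = 0.0081), between the values set for either. That p comes from shuffling hairpins, which are not independent, and measures no spread between libraries.

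Other splits of the same libraries give the scale of chance for each count. For the region difference the splits make chance unlikely without excluding it: 1 of 100 splits, the real one, gave as many as the 60 higher and 95 lower miRNAs (highest other 48). Of 35 splits 1 did in low responders (90, highest other 14) and in high responders (84, highest other 66), the smallest share that 35 splits allow. For the line differences the splits decide nothing, since edgeR called 0 and every split must give as many: 35 of 35 in dorsal raphe (highest other 1), 35 of 35 in amygdala (highest other 99) and 100 of 100 for the interaction (highest other 9). At an unadjusted p under 0.05 edgeR had 70, 65 and 81 miRNAs. In dorsal raphe 1 library out gave 23 (low responder replicate 4), 27 (high responder replicate 2) and 39 to 43 (the other high responder libraries). Without any other low responder raphe library the count was 71 to 76. In amygdala 1 library out gave 46 (low responder replicate 3 or high responder replicate 2) to 102 (high responder replicate 4). DESeq2 called 0, 19 and 17 in the 3 comparisons and limma-voom 0 in each. The split with 99 calls set replicates 1 and 2 of both lines against replicates 3 and 4, which points to a structure of the amygdala samples other than line. It follows the within-group axis, where replicates 1 and 2 of both lines lay at 2.20 to 22.9 and replicates 3 and 4 at -20.8 to -1.56. That axis went with the log2 total, so this structure cannot be told apart from what goes with depth. The labels name no batch. With the number as a block edgeR called 0. Among the 8 splits that part every pair of numbers the highest other count was 0. For the lists chance could not be excluded in dorsal raphe (11 of 35 splits; 1 list, highest other 4), amygdala (33 of 35; 1 list, highest other 14), the interaction (83 of 100; 1 list, highest other 14) or the region difference (8 of 100; 7 lists, highest other 9); of the 8 splits that part every pair in amygdala, 7 gave as many lists (highest other 3).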

How the results depend on the processing

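The alternatives with libraries of over 3000000 counts, the log2 total as a covariate, both shallowest libraries out, the standing-apart raphe library out of the shared spread, 2 low responder libraries out, and the list tests without 1 library were chosen only after the result was seen. The line difference in dorsal raphe gave 0 miRNAs in edgeR under every alternative run, and 0 with DESeq2 and limma-voom (70 at an unadjusted p under 0.05 in edgeR, 22 with library totals, 21 with libraries of over 3000000 counts, and with 1 library out 23, without low responder dorsal raphe replicate 4, to 76; 41, 27, 39 and 43 without high responder dorsal raphe replicates 1, 2, 3 and 4). Of the 53 miRNAs named for the region difference, 1372 of 1479 refits kept direction and side of the threshold; 90 lost the call, all of them of miR-29b-3p, miR-21-5p, miR-219-5p, miR-150-5p, miR-214-3p, miR-32-5p, miR-26b-5p and miR-449a-5p, list members among the 4 of lowest p in their lists. Another 9 passed anew, all of miR-126a-3p. Without 1 library the call was kept in 2 of 16 refits for miR-29b-3p, 3 for miR-21-5p, 5 for miR-219-5p and for miR-150-5p, 7 for miR-32-5p, 8 for miR-214-3p and 10 for miR-26b-5p. DESeq2 gave no adjusted p for miR-10b-5p and miR-10a-5p in the region difference, for miR-485-5p and miR-6331 in dorsal raphe or for miR-485-5p in the interaction. For the line difference in amygdala 267 of 308 refits of named miRNAs kept their side and 41 passed anew, and of 419 for the interaction 19 passed anew, 23 reversed, all of miRNAs below the threshold, and the rest kept theirs.

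The line difference in amygdala, 0 miRNAs in the main analysis, gave 2 with library totals, 19 with DESeq2 and 9 with a mean CPM of at least 10. It gave 30 with libraries of over 3000000 counts, which left high responder amygdala replicates 3 and 4 against all low responder ones. Line thus went in part with replicate number there. The line difference gave 2 with the total as a covariate and 9 with both shallowest libraries out. It gave 2 with the raphe library out of the shared spread and 2 with 2 low responder libraries out. With any 1 amygdala library left out it stayed at 0. The interaction gave 17 with DESeq2, 1 without the low count filter, 1 at an adjusted p under 0.10, 3 with libraries of over 3000000 counts, 1 with the covariate, 3 with both shallowest out and 0 to 1 without 1 library (1 without low responder dorsal raphe replicate 1 or high responder amygdala replicate 4). The region difference gave 303 with the covariate, 244 with 2 low responder libraries out, and 114 (without low responder dorsal raphe replicate 3) to 121 higher and 97 lower (without high responder amygdala replicate 4) with 1 library out. In low responders it gave 220 with libraries of over 3000000 counts, 234 with the covariate and 47 (without low responder amygdala replicate 3) to 84 with 1 library out. In high responders it gave 1.3e2 with DESeq2 (69 higher and 63 lower), 172 with the covariate, 1.4e2 with both shallowest out (86 higher and 52 lower), and 61 (without high responder dorsal raphe replicate 2) to 1.3e2 (72 higher and 56 lower, without high responder amygdala replicate 4) with 1 library out. The cause was not tested, except that a stricter filter leaves fewer miRNAs and leaving libraries out removes samples.

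List calls of camera went to 0 with an estimated correlation in all 4 comparisons, and to 0 with fry in either form for the 3 line comparisons. Dorsal raphe gave 2 with the covariate and 0 (without low responder replicate 1 or 3) to 2 (without high responder replicate 2) with 1 library out. Amygdala gave 2 with the replicate block, 0 with libraries of over 3000000 counts and 1 to 5 with 1 library out (5 without high responder replicate 3, 2 without low or high responder replicate 4). The interaction gave 0 with the replicate block, with libraries of over 3000000 counts and with the covariate, and 0 to 1 with 1 library out (0 without low responder dorsal raphe replicate 1 or 3, low responder amygdala replicate 4 or high responder amygdala replicate 4). The region difference gave 3 with libraries of over 3000000 counts and 3 (without low responder amygdala replicate 2) to 7 with 1 library out. The cause was not tested.

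With the replicate block no other count moved by over 1.5 times, and the region difference gave 168 miRNAs with it, 86 in low responders and 84 in high responders. Outside amygdala the numbers were not shown to pair libraries, since same-numbered libraries had correlations from -0.29 to 0.67 and did not each correlate best with their own number. Nor did they all in amygdala, where low responder replicate 3 went best with high responder replicate 4, and pairing rests there on each correlation being above 0.1 alone. The shared order of the numbers along the main within-group axis could meet that criterion without true pairs.

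miR-101a-3p in amygdala kept its negative sign, below the threshold, under every alternative run, from -0.42 (without low responder replicate 1) to -0.13 (without low responder replicate 4) with 1 library out. Elsewhere the miR-101 miRNAs, never past the threshold, reversed. In dorsal raphe miR-101a-3p and miR-101b-3p had 0.12 and 0.095 with library totals, 0.57 and 0.52 with libraries of over 3000000 counts, 0.49 and 0.44 with both shallowest out, 0.39 and 0.34 with 2 low responder libraries out, and with 1 library out -0.47 and -0.49 (without low responder replicate 1) to 0.53 and 0.49 (without low responder replicate 4). The interaction of miR-101a-3p was -0.075 with RLE factors, -0.49 with library totals, -0.095 with DESeq2, -0.29 with limma-voom, -0.053 without the filter, -0.25 with the replicate block, -0.97 with libraries of over 3000000 counts, -0.32 with the covariate, -0.87 with both shallowest out, -0.58 with 2 low responder libraries out and -0.88 (without low responder dorsal raphe replicate 4) to 0.093 (without low responder dorsal raphe replicate 1) with 1 library out. Its region difference was 0.094 with a mean CPM of at least 10, 0.14 with libraries of over 3000000 counts, 0.31 with both shallowest out, 0.050 with 2 low responder libraries out and -0.29 to 0.18 (without low responder dorsal raphe replicate 4) with 1 library out; that of miR-101b-3p was 0.024 with libraries of over 3000000 counts, 0.18 with both shallowest out and -0.41 to 0.037 (without low responder dorsal raphe replicate 4) with 1 library out. Library totals in place of TMM factors moved the median of all miRNAs from -0.06 to 0.14 in dorsal raphe and from 0.09 to -0.24 in the interaction, so values this small turn with the scaling. Depth limits levels under 0.369 to 1.72 CPM, and at the spread seen edgeR recovered few line differences of 1.5-fold in simulated counts (6.45% in dorsal raphe).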

Other observations

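The values and tests of this part were all chosen only after the result was seen. Low responder amygdala libraries differed among themselves in whole groups of miRNAs. The serotonin 2C receptor gene miRNAs averaged 6.34 ± 1.42 log2 CPM over the 4 libraries (SD), against 6.92 ± 0.51 in high responders, and the choroid plexus and ciliated cell miRNAs 5.29 ± 1.36 against 6.43 ± 0.28. In low responder amygdala replicate 4 miR-1298 stood at 1092 CPM, miR-448-3p at 42.3 CPM and miR-34b-5p at 26.7 CPM, the first within its range in the raphe libraries of high responders (720 to 1983 CPM) and the others below theirs, while miR-1298 stood at 38571 CPM in replicate 2.

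Deviations of the 2 arms of a hairpin from the mean of a group's 4 libraries had r across 113 hairpins of 0.743, 0.627 and 0.744 in low responder amygdala replicates 2, 3 and 4, and 0.094 in replicate 1. Such deviations share 1 mean, so 1 library's deviation is mirrored in the others. Measured without replicate 4, r was 0.262, 0.334 and 0.324 in replicates 1, 2 and 3. In the 4 high responder amygdala libraries r lay between -0.134 and -0.024, and in the 8 raphe libraries between 0.0148 and 0.447, with the same limit. Hairpins are not independent replicates, since clustered ones are made from 1 transcript.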
